A study of Homo sapiens with 8 samples.

How the data were processed

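Ago2 CLIP and RNA-seq were made from 293S cells with and without emetine, 8 libraries in all. The one table used holds no column per library. Per the file headers, the authors deposited for each peak its position, strand, transcript region, gene symbol and RefSeq transcript, a normalised average and a ratio of emetine to no emetine, both as logarithms. The values fit the natural log, which the headers do not state, and log2 values were obtained from the natural log of the authors by division. The submitters' processing notes name the build hg19, Bowtie 0.12.8, TopHat and DESeq, with no roles given. The peak caller, the settings and the start convention of the coordinates are not given in the sources used here, and coordinates are printed as listed. Every peak with recovered reads had at least 11 of them over the 6 libraries.

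Adding and subtracting 0.5 times the ratio from the average gives 1 value per treatment. In the data each such value equals the mean over 3 libraries of ln(1 + reads × factor) minus ln(1 + RNA reads × factor). Library factors and whole read numbers that satisfy this were searched for each peak. Whole reads were recovered for 22453 of 22506 peaks (99.8%) within a tolerance of 2e-13 on the natural log scale. Shifted values matched by chance at 2 of 4716 peaks with emetine and 3 of 4970 in the control. On simulated peaks with other factors, 99.7% of peaks were recovered exactly in each treatment and 0% wrongly. The 53 peaks without a match were left out of all tests. The treatment of each value comes from the header, and no antibody was assigned to a library. The value of 1 read was 8.86, 3.00 and 2.81 in emetine libraries 1 to 3 and 8.00, 2.82 and 2.43 in control libraries 1 to 3. It was 2.51 for the emetine and 6.37 for the control RNA library. Of the peaks, 2063 shared all 6 read numbers with another peak of the transcript, and 81.9% of such neighbouring pairs overlapped or touched.

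The test fixed before the data were examined was a count model with the antibody as a block, or limma on log2(value + 1) for normalised values. The deposited unit is no count and the antibodies of the recovered libraries are unknown. The fit was therefore limma 3.58.1 in R 4.3.3 with a trend on log2(reads × factor + 1) of the 6 libraries, with treatment alone, no filter, and Benjamini-Hochberg adjustment at 0.05. No count model was run on the recovered reads. Changes on this scale are differences of mean logarithms and can be smaller or larger than a ratio of read totals; for 1630 peaks (7.26%) the change of the summed normalised values had the opposite sign. Ratios of read totals were scaled by the summed inverse factors of each treatment, with exact binomial 95% intervals, and 0 reads were set at a floor of 3 reads over the 3 libraries of a treatment. For medians of lists, totals under 3 reads were set at 3. Gene lists were fixed before the data were examined: 16 lists, of which 14 had peaks, while the mitochondrially encoded RNAs and the markers of other cell types had peaks in 0 genes. Lists and regions were tested with camera at a correlation of 0.01, with an estimated correlation as the alternative. The limma step was checked on simulated counts with 200 changed peaks. Region shares were compared by exact permutation tests in scipy 1.17.1 with Python 3.11.15, and figures drawn with matplotlib 3.10.9.

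RNA ratios were log2 of (reads × factor + 1) for 1 library per treatment, with exact binomial 95% intervals on the reads. Genes with at least 50 reads over both libraries were counted. A list's median was placed among 10000 random lists drawn from 10 bins of mean RNA value. The median gene had 289 emetine and 111 control RNA reads.

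Named peaks were, by the rule fixed for tables without values per antibody, the 12 largest and 12 most negative deposited ratios among peaks at or above the median average; 1 of these 24 is not reported here. In addition up to 4 members per list with the smallest p, 1 peak per gene, were available for naming, and for RNA the 8 largest and 8 most negative ratios among genes at or above the median. Alternatives covered scaling, filters, the added constant (0.5 and 5), limma-voom, each library left out, depth class, peaks with reads in at least 3 libraries, identical peaks and sums per gene. Tests between antibodies and of microRNA seed sites were left out, since antibodies were not assigned and a genome sequence of the build was not used here.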

Results

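Ago2 is the Argonaute protein that holds microRNAs on their target transcripts. It was crosslinked to RNA and immunoprecipitated (CLIP) from 293S cells, a derivative of the human embryonic kidney line HEK293. The cells were untreated or had been exposed for 60 minutes to 20 µg/mL emetine, an alkaloid that blocks translation elongation. The design compared Ago2 binding to RNA with and without this treatment, next to the abundance of the same RNAs. There was 1 culture per treatment. It was split into 3 aliquots for CLIP, each with another Ago2 antibody, and 1 aliquot for RNA-seq, so there were 3 CLIP libraries and 1 RNA library per treatment. No p-value below therefore measures the spread between cultures. Those of single peaks and genes, of fry and of region shares rest on the spread between aliquots and antibodies. Those of camera compare the peaks of a list or region with all other peaks, under a preset or estimated correlation.

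The authors' deposited table listed 22506 peaks in 6326 genes. Of these, 12955 (57.6%) lay in 3' UTRs, 7476 (33.2%) in coding sequence, 1115 (4.95%) in 5' UTRs and 960 (4.27%) in exons of noncoding transcripts. The median peak width was 30 nt. Read numbers per library were recovered from the deposited values for 22453 peaks. They came to 39871, 103294 and 95025 reads for emetine libraries 1 to 3, and 38954, 116488 and 101457 reads for control libraries 1 to 3. These numbers count reads in listed peaks only. The libraries are numbered by the falling value of 1 read after normalisation, library 1 having the fewest reads of each treatment, and their antibodies were not assigned. Over the 6289 genes with recovered values, the RNA library held 3712294 reads with emetine and 1531898 reads in the control. Intervals given below cover counting error only, since amplified reads are not independent molecules.

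The first comparison asked which Ago2 peaks differed with emetine. Peaks with more reads after emetine included those in LMNB1 (lamin B1 of the nuclear lamina), PCNA (the sliding clamp of DNA replication), HSP90AA1 (a cytosolic chaperone) and PSMB6 (a proteasome subunit). Peaks with more reads in the control included 3' UTR peaks of SDC1 (a cell surface proteoglycan), EIF4EBP2 (a repressor of cap-dependent translation) and ZNF224 (a zinc finger protein). None of these differences passed the test. In limma, 0 of 22453 peaks had an adjusted p under 0.05, and the smallest adjusted p was 0.784. At an unadjusted p under 0.05 there were 238 peaks, 171 higher and 67 lower with emetine. This is a smaller share of the peaks than the 0.05 expected with no change. Other splits of the 6 libraries, which mix the treatments, gave 171 to 964 peaks at that level in limma. With limma-voom, 0 peaks passed after adjustment and 545 had an unadjusted p under 0.05. The median standard error of a log2 change was 2.04. In simulated data with the libraries' read depth, the changed peaks were drawn from peaks at or above the median level. At a dispersion of 0.2, 87% of those changed 8-fold and 35% of those changed 4-fold were recovered, with 12 false calls. At a dispersion of 2, 0% of either were recovered. The median dispersions were 1.38 in the emetine and 1.77 in the control libraries. These are moment estimates from 3 libraries each and can lie under the true dispersion.

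Peaks in this and the next paragraph were picked for the most extreme deposited ratios, PCNA for the smallest p of its list. Their ratios therefore tend to be overstated. The coding peak of LMNB1 on chromosome 5 from 126168385 to 126168403 held 6, 42 and 37 reads in the emetine libraries and 0, 0 and 2 in the controls. The ratio of read totals, scaled by depth, was 47.2 (95% exact interval 12.7 to 396), and the log2 change was 5.64 (SE 1.81, n = 3 per group; limma adjusted p = 0.784). A coding peak of PCNA on chromosome 20 from 5095933 to 5095971 held 37, 80 and 46 reads with emetine against 3, 1 and 5 reads, a ratio of 20.1 (95% exact interval 10.3 to 44.8). In the 3' UTR of NHLRC3 on chromosome 13 from 39622284 to 39622315, emetine libraries held 2, 35 and 19 reads and the controls none. Against a floor of 3 reads over the 3 control libraries this is at least 20.7-fold higher. Such bounds, here and below, allow only for the count of 0 in 1 treatment. They cover neither the counting error of the other treatment's reads nor the spread between libraries. Peaks without reads in a treatment were common: 3982 of the tested peaks (17.7%) had no control read and 4540 (20.2%) no emetine read. By the same floor the peaks in the 3' UTRs of WDR1 (an actin disassembly factor), ZMAT3 (an RNA-binding zinc finger protein) and MAPK6 (a kinase) were at least 14.4-fold, 15.6-fold and 12.6-fold higher, with 4, 9 and 26, 3, 35 and 4, and 3, 24 and 7 reads in emetine libraries 1 to 3, so most reads of each came from 1 library. The 3' UTR peak of HMGA2, a chromatin protein whose mRNA is a classic let-7 target, was at least 9.26-fold higher, with 3, 10 and 12 reads against 0. Coding peaks of PSMB6 and of GSR (glutathione reductase) were at least 13-fold and 8.89-fold higher, a 5' UTR peak of the kinase FYN at least 10.0-fold and a 3' UTR peak of ARL10 at least 7.78-fold. TUBB4B, a beta tubulin with close paralogs that may share its reads, had 36 reads in its coding peak with emetine against 2, a ratio of 20.0 (95% exact interval 5.15 to 171). FAM46C had 48 against 9 reads in its 3' UTR peak, a ratio of 5.93 (95% exact interval 2.88 to 13.7).

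In the other direction, the SDC1 peak in the 3' UTR on chromosome 2 from 20401755 to 20401786 held no reads with emetine and 2, 25 and 23 reads in the controls, at least 15.0-fold lower against a floor of 3 reads over the 3 emetine libraries. The 3' UTR peaks of EIF4EBP2, C1orf109, ZNF224, TMEM167B and FKBP15 were at least 14.1-fold, 11.4-fold, 10.2-fold, 8.40-fold and 6.60-fold lower, EIF4EBP2 with 3, 36 and 8 control reads. A coding peak of PHAX, an RNA export adaptor, was at least 7.20-fold lower. ZCCHC3 held 2 reads with emetine against 71 in its 3' UTR peak, a ratio of 0.0313 (95% exact interval 0.00372 to 0.117), and SPSB1 held 1 against 21, a ratio of 0.0529 (95% exact interval 0.00128 to 0.329). A further 2 peaks with negative deposited ratios were in APRT, a purine salvage enzyme. Its 3' UTR peak held 0 reads with emetine against 13, while its coding peak held more with emetine, 10 reads against 1, all 10 in emetine library 3, and is negative only relative to RNA. Their log2 ratios in the authors' deposited table, -8.22 and -4.97, include an RNA value for APRT. It was recovered as 18 reads with emetine and 0 in the control. The limma adjusted p was 0.784 for each peak named in this and the preceding paragraph, except the APRT coding peak at 0.965.

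**Figure D1:**
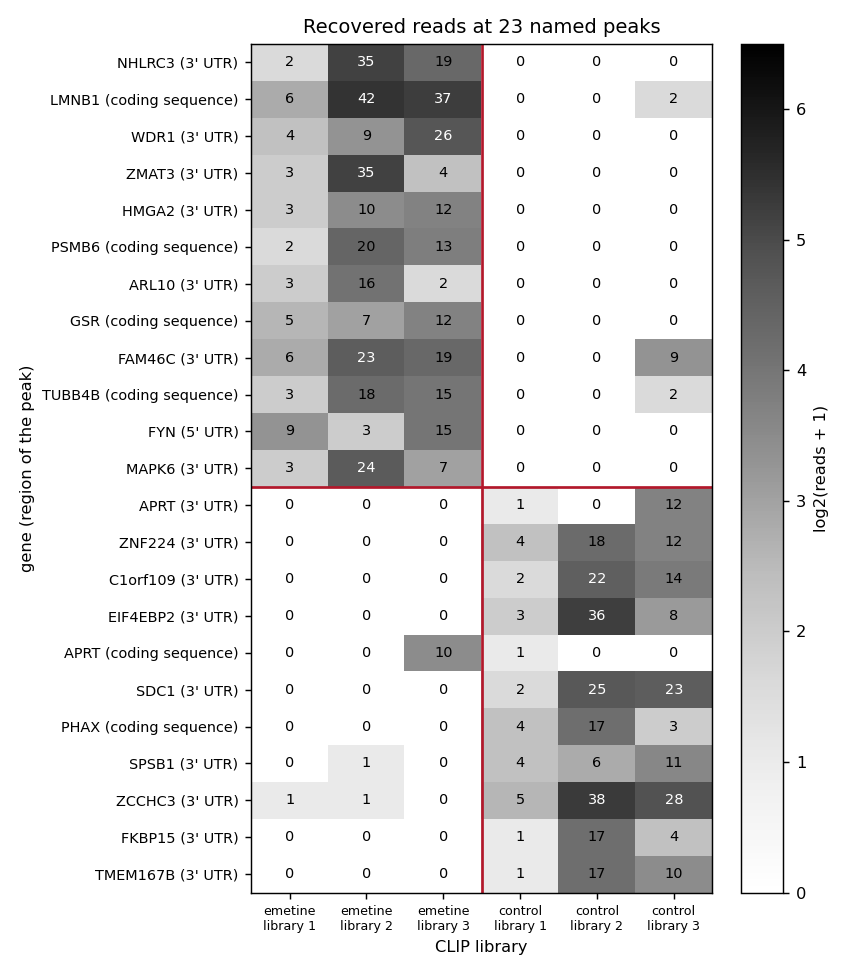
Recovered reads at 23 of the 24 peaks with the largest positive (upper block) and negative (lower block) deposited log ratios among peaks at or above the median level; columns are the 6 CLIP libraries and shading is log2(reads + 1). The LMNB1 row holds 6, 42 and 37 reads with emetine and 0, 0 and 2 in the controls.

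Summed over all peaks of a gene, the smallest p-values belonged to TXNIP, ZNF367, ZNF711 and PCNA, which were picked after their values were seen. TXNIP, an arrestin-like regulator of glucose uptake and a target of the miR-17 family, held 45, 368 and 430 reads with emetine against 10, 155 and 129 over 31 peaks, a ratio of 3.19 (95% exact interval 2.79 to 3.65). For ZNF367 the ratio was 2.71 (95% exact interval 2.33 to 3.16), for ZNF711 1.80 (95% exact interval 1.67 to 1.94) and for PCNA 5.66 (95% exact interval 4.1 to 8.0). None passed, the limma adjusted p being 0.798 for each, and 0 genes had an adjusted p under 0.05, with 116 at an unadjusted p under 0.05.

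Gene groups were then compared. Peaks in transcripts of replication-dependent histones and of heat shock proteins and chaperones were more often higher than lower with emetine, but whether these lists passed depended on the correlation assumed between peaks and on single libraries. Of 111 histone peaks in 33 genes, 76 were higher with emetine and 35 lower, with a median log2 change of 0.60, or 1.10 as a ratio of read totals with fewer than 3 reads set at 3. Relative to RNA, the median log2 ratio of the authors' deposited table was 0.31 for these peaks. Examples are coding peaks of HIST1H1E, a linker histone, with 5, 1 and 11 reads against 0, and of HIST1H2AG, with 1, 9 and 6 reads against 0; HIST1H1C had 25 against 4 reads and HIST1H2AE 19 against 2. Histone genes are near-identical copies, so reads can be shared among them. Of 120 chaperone peaks in 29 genes, 79 were higher and 41 lower, with a median log2 change of 0.84, or 0.98 as such a ratio of read totals, and a median deposited log2 ratio relative to RNA of 0.60. Here HSP90AA1 had 7, 2 and 30 reads against 0 in a coding peak, DNAJA2, a co-chaperone, 45 against 1, CCT7, a chaperonin subunit, 23 against 0, and the 5' UTR of HSPA1B, which shares sequence with HSPA1A, 43 against 4. Both lists had an adjusted p of 0.0368 in limma's camera test with a preset correlation of 0.01. With an estimated correlation neither call held, at an adjusted p of 0.669 for each list and an unadjusted p of 0.207 for the histones and 0.130 for the chaperones. Tested against no change instead of against other peaks, with limma's fry, each list had an adjusted p of 0.630. The histone call was also lost without emetine library 1 (adjusted p = 0.0556, limma), emetine library 3 (0.327), control library 1 (0.0558) or control library 2 (0.218). The chaperone call was lost without the same libraries, at limma adjusted p-values of 0.101, 0.0894, 0.0861 and 0.159. Among peaks with reads in at least 3 libraries the adjusted p was 0.104 for the histones and 0.206 for the chaperones in limma.

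The other 12 lists did not pass with all 6 libraries and all peaks. Peaks of ATF4 and unfolded protein response genes were lower on balance, with 101 of 181 lower and a median log2 of -0.49 (camera adjusted p = 0.0822, limma). This list passed as lower without emetine library 2 (0.0453) and among peaks with reads in at least 3 libraries (0.0233), and had an adjusted p of 0.669 with an estimated correlation and all libraries. In that list a coding peak of CANX, the chaperone calnexin, held 0 reads against 4, 25 and 4, while a 3' UTR peak of the amino acid transporter SLC7A5 held 30 reads against 4. Immediate early and short-lived mRNAs had a median log2 of 0.62 (214 peaks) and a median deposited log2 ratio relative to RNA of 0.18, with 39 against 8 reads in a 3' UTR peak of the survival gene MCL1. The camera adjusted p from limma was 0.158 for these, for tubulins and actins (median log2 0.48) and for splicing regulators (0.37). Splicing regulators passed as higher without control library 1 (0.00984) or emetine library 2 (0.0234), and tubulins and actins without emetine library 2 (0.0448), and with an estimated correlation and all libraries each of these lists had 0.669. With all libraries the camera adjusted p from limma was 0.315 for glycolysis (1.36), 0.394 for cytosolic ribosomal proteins (0.28) and for miR-17 family targets (0.34), 0.401 for translation factors (0.10) and the cell cycle (0.33), 0.443 for let-7 targets (-0.14), 0.535 for proteasome and ubiquitin genes (0.06) and 0.806 for the miRNA machinery (0.10). Of the 31 glycolysis peaks, 17 were higher and 14 lower, with a mean log2 change of 0.56, and 15 had no read in 1 treatment. As a ratio of read totals with fewer than 3 reads set at 3, instead of a mean of logarithms, the median log2 was -0.25 for proteasome and ubiquitin genes, 0.29 for tubulins and actins and -0.38 for let-7 targets. Within the machinery list, a 3' UTR peak of TNRC6A, the GW182 partner of Ago2, held 25 reads with emetine against 1, whereas 3' UTR peaks of DICER1 and of EIF2C1, which encodes Ago1, held 0 against 21 and 22. Cell cycle members also went both ways, with WEE1 at 50 against 28 reads and E2F3 at 3 against 69 reads in 3' UTR peaks. In each list tested, 0 peaks passed when adjusted over the list alone, as over all peaks.

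Coding sequence and 3' UTRs were compared because emetine acts on translating ribosomes. Coding peaks had a median log2 change of 0.29 (7458 peaks) and 3' UTR peaks of -0.17 (12947 peaks). Neither difference passed, with a camera adjusted p of 0.223 in limma for both regions, and 5' UTR and noncoding exon peaks had 0.418. Without control library 1, 3' UTR peaks passed as lower (0.00435) and 5' UTR (0.00102) and noncoding exon peaks (4.1e-09) as higher. Noncoding exon peaks also passed as higher without emetine library 2 and as lower without emetine library 1 or control library 2. With an estimated correlation and all libraries the adjusted p was 0.804 for 3' UTR and coding peaks. In the shares of reads, coding peaks took 16.3%, 33.8% and 28.3% in emetine libraries 1 to 3 and 16.8%, 27.0% and 24% in control libraries 1 to 3. The 3' UTR peaks took 30.9%, 56.5% and 54.7% with emetine and 32.2%, 64.1% and 60.1% in the control (two-sided exact permutation p = 0.5, adjusted 0.8). The mean coding share was 26.1% ± 8.95 (SD, n = 3) with emetine and 22.6% ± 5.25 (SD, n = 3) in the control (two-sided exact permutation p = 0.6, adjusted 0.8 over 4 regions). The smallest p that 3 against 3 libraries allow is 0.1. Within the deeper libraries the mean coding share was 31.0% against 25.5%, and in the shallowest libraries 16.3% against 16.8%. Noncoding exons held 45.6% (Wilson 95% interval 45.2 to 46.1) of reads in emetine library 1 and 43.0% (42.5 to 43.5) in control library 1, but 6.01% and 12.9% in the other emetine and 6.03% and 12.3% in the other control libraries.

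**Figure D2:**
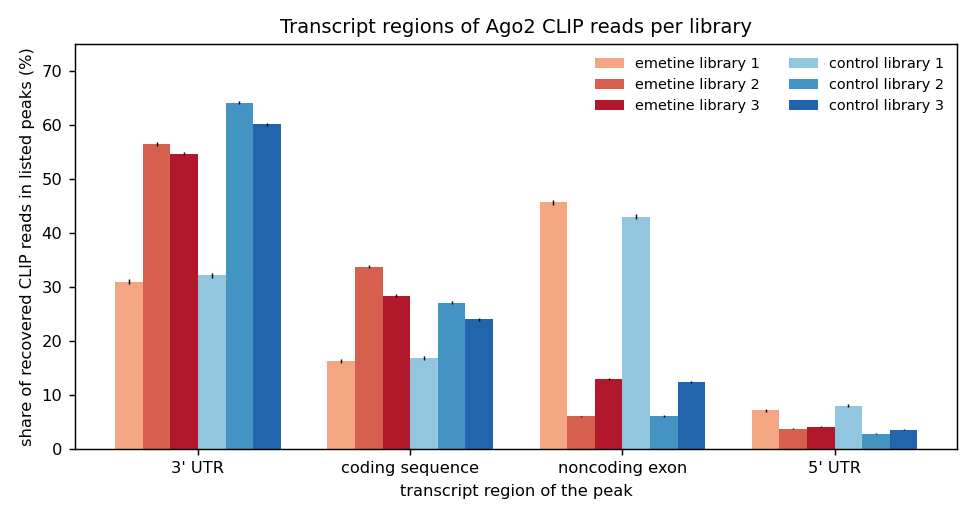
Share of recovered CLIP reads by transcript region of the peak (percent, y axis) in each of the 6 libraries, with Wilson 95% intervals. Library 1 of each treatment stands apart, with 45.6% and 43.0% of its reads in noncoding exons.

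RNA abundance was compared between 1 library per treatment, so no gene was tested and no difference has a replicate check. TXNIP and JUN (an immediate early transcription factor) were higher after emetine, and small nucleolar RNAs were mostly lower. Of 31 histone mRNAs, 24 had a log2 ratio above 0. Some of these were within counting error, such as HIST1H1C at 0.11 (95% exact interval -0.10 to 0.32). TXNIP had 573 reads with emetine and 54 in the control, a log2 ratio of 2.06 (95% exact interval 1.66 to 2.49). Among genes at or above the median RNA value, TXNIP was highest and the next values were 1.28 for JUN (1391 and 225 reads), 1.28 for HIST1H2AL, 1.24 for HIST1H1D, 1.11 for HIST1H2AH, 1.05 for ZNF12, 1.00 for ZNF367 and 0.90 for ZBTB24. At the other end of these genes, the small nucleolar RNA SNORA25, which guides RNA modification, had 149 and 794 reads, a log2 ratio of -3.75 (95% exact interval -4.02 to -3.50). SNORA63, SNORA44, SNORA38 and SNORA38B had log2 ratios of -2.89, -2.52, -2.38 and -2.28, SNORA23 -1.52 and SNORD22 -1.49. ALDOA, the glycolytic aldolase, was the only mRNA among the 8 lowest, at -1.61 (854 and 1027 reads). Of 5780 genes with at least 50 RNA reads, 49 had a log2 ratio above 1 and 44 below -1, and the SD across genes was 0.35.

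Gene lists were placed among random lists from the same 2 libraries, which compares genes and not cultures. The median log2 ratio of immediate early and short-lived mRNAs was 0.64 over 24 genes, at percentile 100 of 10000 random lists matched on mean expression, 18 genes were above 0 and 7 exceeded 1, including ATF3 (1.18), ID2 (1.14), HES1 (1.12), TRIB1 (1.12) and MYC (1.03). Replication-dependent histones had a median of 0.25 over 31 genes (percentile 99.99), with 7 genes above 1 and HIST1H2AC lowest at -0.62 (95% exact interval -0.82 to -0.41). Reads can be shared among these near-identical copies, so their ratios may not be independent, which the random lists do not take into account. The RNA of HSPA1B was at 0.76, while the chaperone list had a median of 0.08 (percentile 96.6). Cytosolic ribosomal protein mRNAs had a median of -0.12 over 48 genes (percentile 0.13).

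**Figure D3:**
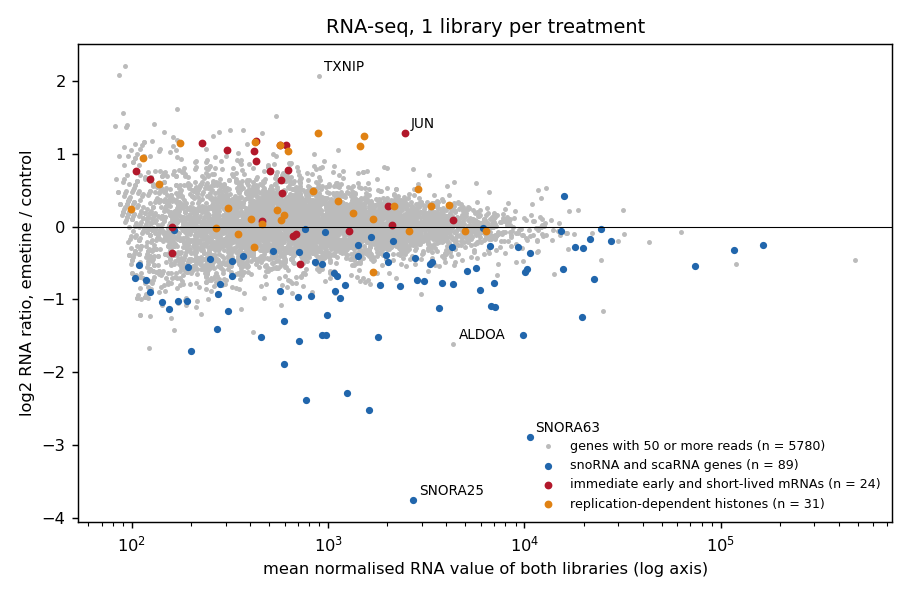
Log2 ratio of RNA values, emetine over control (y axis), against the mean normalised RNA value (log x axis) for 5780 genes, 1 library per treatment. Immediate early mRNAs (red) centre at 0.64 and TXNIP lies at 2.06, and small nucleolar RNAs (blue) extend down to -3.75.

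By the structure recovered from its values, the authors' deposited table gives the CLIP change relative to the RNA change, although it has no RNA column. In it 7696 peaks (34.2%) had a log2 ratio above 1 and 7460 (33.1%) below -1, and none of them passed the CLIP test. Noncoding exon peaks had a median log2 ratio of 0.63 in the authors' deposited table, against 0.12 for their CLIP change without the RNA term. TXNIP had an RNA ratio of 4.17-fold and a CLIP ratio over its peaks of 3.19-fold. Across 1038 genes with at least 100 CLIP reads and 50 RNA reads, CLIP and RNA log2 changes had a Pearson r of 0.0937 and a Spearman rho of 0.0881, where genes are not independent replicates. The SD of the CLIP change across these genes was 0.92 and that of the RNA change 0.31.

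Agreement between the CLIP libraries was low. Across peaks, which are not independent replicates, the 6 pairs of libraries of the same treatment had Pearson correlations of log2 values from -0.13 to 0.20, with a mean of 0.0505. The 9 pairs across treatments ranged from -0.17 to 0.48, with a mean of 0.0765, the highest being emetine library 1 with control library 1. Every peak had at least 11 reads over the 6 libraries, and this selection can lower the correlations. Among peaks with reads in 4 or more libraries the mean was 0.107 within and 0.132 between treatments. Reads were found in exactly 1 library at 5951 peaks (26.5%), in 2 at 6343, and in all 6 at 1035 (4.61%). Reads in 1 or 2 libraries were found at 12294 peaks (54.8%).

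**Figure D4:**
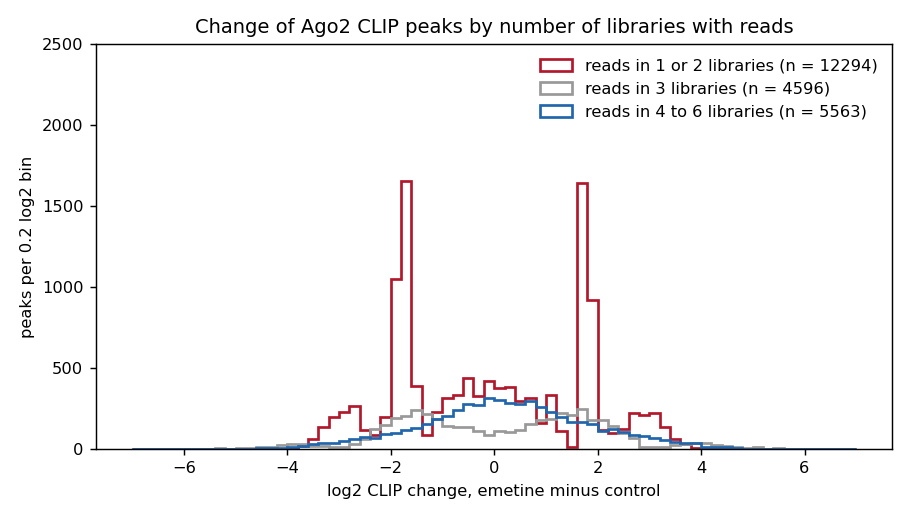
Number of peaks (y axis) per bin of log2 CLIP change, emetine minus control (x axis), by the number of the 6 libraries with reads at the peak. Peaks with reads in 1 or 2 libraries (12294, red) gather on both sides of 0, and peaks with reads in 4 to 6 libraries (5563, blue) centre near 0.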

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

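The settings with reads in at least 3 libraries, depth class, identical peaks, summed reads per gene, summed values and total RNA reads were chosen after seeing the data. No pairing by antibody was fitted, since no antibody was assigned to a library. DESeq2, the comparison between antibodies and the seed tests were not run. All 17 alternatives of the peak test gave 0 peaks past the adjusted threshold, with 1 to 545 at an unadjusted p under 0.05 (428 with depth class as a block). The count of gene lists, 2 as reported, was 0 with an estimated correlation, 1 with reads in at least 3 libraries and 0 to 5 with each library left out, and stayed at 2 in the 4 other settings. The 1 list was ATF4 and unfolded protein response, lower (0.0233), while histones (0.104) and chaperones (0.206) did not pass there. The highest count, 5, came without emetine library 2, where ATF4 and unfolded protein response (0.0453), tubulins and actins (0.0448) and splicing regulators (0.0234) joined both; without control library 1 the 1 list was splicing regulators (0.00984). The count of regions, 0 as reported, was 0 to 3 with each library left out, 3 without control library 1 and 1 without emetine library 1, emetine library 2 or control library 2. With a library left out, the camera adjusted p of noncoding exons ranged from 4.1e-09 to 0.843, in both directions. That of 5' UTRs ranged from 0.00102 to 0.843, also in both directions. The 3' UTRs passed as lower without control library 1 (0.00435). Removing a library unbalances the shallow and deep libraries, but whether this moved the calls was not tested. Leaving out emetine library 3 (0.147 for noncoding exons) or control library 3 (0.843) also unbalances them, and no region passed. Directions also turned for lists without a call: the miRNA machinery (0.383 to 0.890 with a library left out, 0.736 with 1 peak per gene, 0.762 with summed reads), ribosomal proteins (0.196 to 0.735) and translation factors (0.128 to 0.716). Deposited log2 ratios above 1 numbered 7696, 3152 above 2 and 3525 with reads in at least 3 libraries; below -1 they were 7460, 2877 below -2 and 2647. RNA genes past a log2 ratio of 1 numbered 93, and 189 with no filter on reads, which adds genes with few reads. The cause of these changes between settings was not tested. Depth limits the resolution of single reads: 1 read against 0 moves a log2 change by 1.10 in emetine library 1 and by 0.643 in emetine library 3.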

Other observations

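The tests on pairs of libraries, on treatment-specific binding, on the number of libraries with reads and on the shallowest pair were chosen after related values had been seen, as were the snoRNA and zinc finger groups.

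Small nucleolar and Cajal body RNAs were mostly lower with emetine in the RNA libraries. Of 89 such genes with at least 50 reads, 88 had a log2 ratio below 0 and 25 below -1, with a median of -0.71, and SNORA27 was the exception at 0.41. Zinc finger genes named ZNF went the other way, with 103 of 145 above 0, a median of 0.17 and ZNF853 highest at 2.21. Glycolytic mRNAs had a median of -0.20 over 12 genes, at percentile 0.88 of matched random lists, led by ALDOA. Tubulin and actin mRNAs had a median of -0.13 (percentile 3.41), with TUBA1C lowest at -0.60. These values come from 1 library per treatment, and the size selection of small RNAs is not given in the sources used here.

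Reads at a peak came mostly from 1 library, a median of 78.6% of them. Sequencing depth alone is argued against: among peaks with 11 or more reads in the other 5 libraries, the share with any read in a given library lay at least 44.8 percentage points under the Poisson share (-44.8 to -74.4). Selection by the minimum total is argued against in the same way, since the gap was -34.0 to -60.1 points among peaks with 4 or more reads in at least 2 other libraries. Binding specific to an antibody under both treatments, as the sole explanation, would need 3 matching pairs, but in the pairing with the highest weakest pair that pair reached 0.458 of the Poisson share. In the 2 pairings that join emetine library 1 with control library 1, which reached 0.971, the weakest pair reached 0.266 and 0.320. These pairs are not compared at like levels, since 11 reads stand for a higher normalised value in library 1. Only 577 peaks in emetine library 1 and 636 in control library 1 had them. Those of emetine library 1 also reached 0.906 in emetine library 3, 0.913 in control library 3 and 0.744 in both libraries 2. Binding specific to the treatment, as the sole explanation, would need sharing near the Poisson share within each treatment, but emetine libraries 2 and 3 reached 0.375 of it and control libraries 2 and 3 0.337. The mean within treatments minus that between treatments decides nothing, since it was -0.0225 with all pairs and 0.0345 without emetine library 1 with control library 1. A mixture of both kinds of binding, or of either with uneven amplification, was not tested. The Poisson share leaves no room for other noise, so a partial role of antibody or treatment stays open. Noncoding exon shares were alike in emetine and control library 1 (45.6% and 43.0%), library 2 (6.01% and 6.03%) and library 3 (12.9% and 12.3%). Amplification of few crosslinked molecules may remain as a source and was not tested, because the values carry no molecule identifiers.

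The log2 CLIP changes formed modes on both sides of 0. A candidate explanation is that peaks filled by 1 or 2 libraries produce them through the added constant of 1. The density in the modes relative to the centre was 0.458 for peaks with reads in 4 or more libraries and 2.08 for peaks with reads in 1 or 2. This decides nothing, because a peak with reads in 1 library cannot lie near 0. An absolute log2 change above 1 was found at 100% of peaks with reads in 1 library, 47.2% in 2, 72.4% in 3 and 51.2% in 4 to 6. Peaks with reads in 1 library thus add to both sides of 0 by construction. For peaks with reads in more libraries the explanation stays open. No biological explanation was tested.

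The coding share of coding and 3' UTR reads was 6.66 points higher with emetine in the deeper libraries. A few abundant peaks are argued against, because the difference was 6.92 points without the 1% of peaks with most reads. Genes with only coding or only 3' UTR peaks are argued against as the source, because it was 6.05 points within the 2041 genes with both kinds of peak. A shift of reads among those 2041 genes is not excluded by this. An effect of emetine may be the source and stays open: the shallowest pair differed by 0.159 points, within counting error. Over all 3 against 3 libraries the difference was 4.49 points, with an exact permutation p of 0.2. Whether the difference belongs to the treatment or to its single culture cannot be told apart.

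The 10 splits of the 6 libraries are too few for a share under 0.05. For peaks past the threshold the real split gave 0 and the highest other 18. That split joined emetine libraries 1 and 3 with control library 1, and the split that joined emetine library 1 with control libraries 1 and 3 gave 15. The 7 remaining splits gave 0, as did the real one, and 2 of these 7 also join emetine library 1 with control library 1. The 2 higher counts may reflect a structure of the libraries other than treatment, which was not tested. For gene lists the real split gave 2 and the highest other 2.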
